A study of Mus musculus with 13 samples.

How the data were processed

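Single-cell 5′ RNA libraries with T-cell receptor capture (10x Genomics) were made from live CD3+ cells sorted from tumours of mice injected with MCA205 cells, and only the gene expression counts are used here. As deposited by the authors, each of the 13 files holds raw UMI counts per gene and barcode with no normalization, counted by the authors with Cell Ranger against mm10. Per the file headers, replicate 1 libraries were counted with version 3.0.2, or 3.1.0 for Prdm1 KO, and replicate 2 libraries with version 7.0.0, which counts intronic reads by default, while the processing notes name version 3.0.2 throughout. Barcode lists, gene identifiers and symbols as deposited by the authors are given per the file headers of the same software. The WT replicate 1 files hold all 737280 barcodes of the kit and the others a filtered list whose lowest barcode has 500 to 502 UMIs. The WT replicate 2 files list 32285 genes and the others 31053, and the 30406 genes common to all were kept. Total UMIs per file in untreated and treated libraries were 43217003 and 55307126 for WT replicate 1, 128602555 and 88408307 for WT replicate 2, 42522613 and 46643234 for Cd4Cre replicate 1, 49388015 and 48047779 for Bcl6 KO replicate 1, and 21254126 and 31624165 for Prdm1 KO replicate 1. The untreated replicate 2 totals were 39741175 for Cd4Cre, 31662226 for Bcl6 KO and 38904270 for Prdm1 KO.

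Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, 106527 cells in all, with median UMIs per cell between 2285 and 5665 by library. The highest scrublet scores were removed as doublets at 0.8% per 1000 cells, 8253 cells or 2.71% to 14.0% by library, since scrublet's own threshold called 0 to 3 cells in 12 of the libraries and 2483 in untreated WT replicate 2. All 106527 cells were clustered with the Leiden method of igraph on 2000 variable genes, 30 principal components and 15 neighbours at resolution 1. The variable genes came from scanpy 1.11.5. Doublets stayed in this clustering, and the other 98274 cells were counted in the classes as reported. A harmony-style correction by library was added after a first clustering, seen in the data, parted cells by Cell Ranger version. The 23 clusters were cut into 190 sub-clusters, and each was named by detection of Cd4, Cd8a, Cd8b1 and Foxp3. A sub-cluster was CD4 where at least 30% of cells had a Cd4 UMI and CD8 where at least 40% had a Cd8b1 UMI, each at least 2.5 times the share of the other lineage. CD4 sub-clusters were Treg-like with Foxp3 in at least 40% of cells and conventional under 15%. A sub-cluster whose leading genes were markers of another type, or with fewer than 3 of its own markers detected, stayed unnamed. This gave 22688 CD4 Tconv-like, 17028 Treg-like, 24019 CD8 T-like, 722 γδ, 7742 other and 26075 unnamed cells, and a library entered a test with at least 20 cells of the class. Cells are not replicates, so UMIs were summed per library and class.

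Each class was tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling, filterByExpr and robust two-sided quasi-likelihood F tests over 8 group means and all 13 libraries, at a Benjamini-Hochberg adjusted p of 0.05 over 12529 genes in CD4 Tconv-like, 11522 in Treg-like and 12781 in CD8 T-like cells. Groups with 1 library are assumed to vary like the others. Comparisons were anti-CTLA-4 minus untreated in WT and as the mean over 4 genotypes, Prdm1 KO and Bcl6 KO minus Cd4Cre in untreated libraries, and, in CD4 Tconv-like cells, the difference of treatment effects. The labels number replicates without saying what the numbers mean. Deviations of replicate 2 from its group mean correlated across genes between groups at 0.405 to 0.774 in CD4 Tconv-like, 0.333 to 0.813 in Treg-like and 0.418 to 0.816 in CD8 T-like cells. Libraries of one number thus share differences, whose source (processing, experiment or animals) was not separated, and genes are not independent replicates. In each class the lowest correlation was between untreated WT and untreated Cd4Cre. The highest was between the WT groups or, in Treg-like cells, between untreated Bcl6 KO and untreated Cd4Cre. A single term for the replicate number may therefore not remove these differences alike in all groups. The 16 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, whose p tests whether a list's genes move on balance one way and whose mixed p tests change in either direction. The 12 marker lists of cell types were only counted. List p-values were adjusted over the 64 tests of a class, and the differences of effects over their own 32. Shares were compared by exact two-sided permutation. Within-replicate ratios use an offset of 0.5 CPM, intervals are at 95%, and folds against libraries at 0 use a floor of 3 counts per library. Scaling by DESeq2's size factors moved the median of all genes by at most 0.03 in log2. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

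The tests were tested on simulated data with 100 genes changed 2-fold or 4-fold. In CD4 Tconv-like cells 0% and 1% of them were recovered for WT, 17% and 89% for the mean of 4 genotypes, 0% and 1% for Prdm1 KO, and 0% and 6% for Bcl6 KO. In Treg-like cells these were 0% and 15%, 19% and 87%, 0% and 26%, and 2% and 20%. In CD8 T-like cells these were 0% and 14%, 24% and 93%, 1% and 24%, and 0% and 27%. False calls were 0% to 21.4% of all calls, and 0 of 20 unchanged lists were called in each. The simulated genes varied independently and had no shared replicate difference, so this does not check the list tests on correlated genes.

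Groups, lists, tests, alternatives and the rule for naming genes were set before the data were examined. The rule names 19 core genes in every CD4 Tconv-like comparison, then the list genes past the threshold with the 8 largest rises and 8 largest falls and the 5 largest of each among other genes, and in the other classes the core genes that pass and the 5 largest of each. All other named genes, such as examples of lists, genes called in the blocked fit and the MHC class II genes, were chosen after their values were seen. Some genes that this rule or the lists would name are not reported here. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, at least 2000 UMIs per cell, doublets kept, classes from UMI gates, the blocked fit, each library left out, only the libraries of a comparison, and 3 untreated and treated libraries against 3. Those chosen after seeing the data were all sub-clusters with a clear lineage, no cycling cells, 5 pairs of one genotype and replicate number, and the 8 replicate 1 libraries alone. The 26075 unnamed cells, γδ T cells, other cells and T-cell receptor sequences were left out of the comparisons. Xist stood between 219 and 794 CPM in all libraries and classes, and Ddx3y and Eif2s3y at 0.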

Results

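The data are single-cell 5′ RNA counts from T cells of mouse tumours. Live CD3+ cells were sorted from subcutaneous MCA205 tumours, a fibrosarcoma line, grown in C57BL/6J mice that were wild type (WT) or carried transgenes. Per the labels, treated mice received an antibody against the inhibitory receptor CTLA-4, clone 4F10-IgG2a, at 100 µg on days 6 and 9, and tumours were taken on day 10, while the series text names days 6, 9 and 11. The 13 libraries fall into 8 groups. The untreated WT, anti-CTLA-4 WT, untreated Cd4Cre, untreated Bcl6 KO and untreated Prdm1 KO groups hold 2 libraries each. The anti-CTLA-4 groups of Cd4Cre, Bcl6 KO and Prdm1 KO hold 1 library each. Total UMI counts per library ran from 21254126 in untreated Prdm1 KO replicate 1 to 128602555 in untreated WT replicate 2, and between 3364 and 17450 cells per library passed the filters. The cells compared were 22688 conventional CD4 cells (CD4 Tconv-like), 17028 regulatory T cells (Treg-like) and 24019 CD8 T-like cells. Replicate 1 and replicate 2 libraries were counted with different Cell Ranger versions per the file headers, so values are also given within each replicate number and from a second fit with the replicate number as a term (the blocked fit). The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries. Intervals and floors cover counting error only. Levels are given in CPM, counts scaled to a common library total with TMM factors, as mean ± SD over libraries.

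The targeted genes came first. Prdm1 encodes the transcription factor Blimp-1 and Bcl6 encodes a repressor that opposes it. Prdm1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501, mm10) was higher, not lower, in the libraries labelled Prdm1 KO. In CD4 Tconv-like cells it stood at 130.4 and 99.7 CPM in the untreated Prdm1 KO replicates and 143 CPM in the treated one. The other 10 libraries held between 18.3 and 32.4 CPM. In Treg-like cells the labelled libraries held 534, 395 and 304 CPM against 51.6 to 115 CPM elsewhere. In CD8 T-like cells they held between 84.1 and 104 CPM against 18.3 to 39.7 CPM elsewhere. Bcl6 (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852) was not lower either, at 16.8, 39.5 and 18.9 CPM in CD4 Tconv-like cells of the libraries labelled Bcl6 KO. It was below that in each matching Cd4Cre library, at 13.7, 28.6 and 7.79 CPM, and stood at 6.88 to 27.9 CPM in WT. The deleted exons are not given and UMIs are summed per gene from 5′ ends, so the level does not check a deletion.

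**Figure D1:**
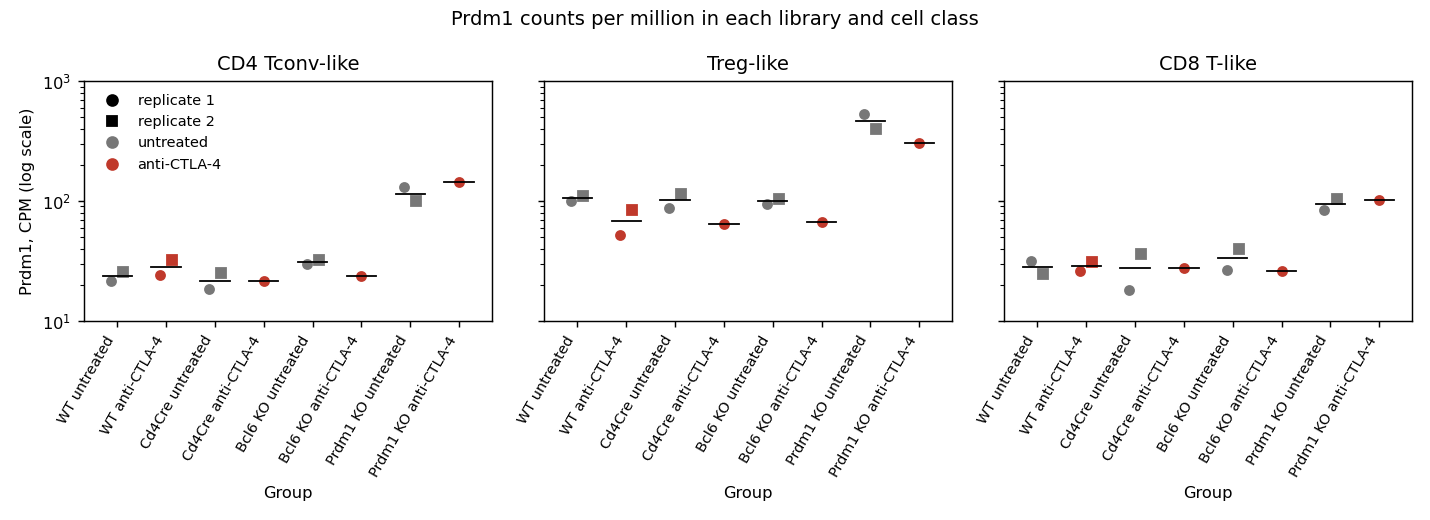
Prdm1 CPM (log scale) in each library, for 3 cell classes, with replicate 1 as circles, replicate 2 as squares and a line at the group mean. The 3 libraries labelled Prdm1 KO stand between 99.7 and 143 CPM in CD4 Tconv-like cells, above the highest other library at 32.4 CPM.

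Anti-CTLA-4 lowered the regulatory share of CD4 cells. This comparison asks how treatment changed the make-up of the infiltrate. Treg-like cells, which restrain other T cells, made up 47.6% and 74.6% of CD4 cells in the untreated WT libraries (61.1 ± 19.1, SD, n = 2) and 13.1% and 19.8% after treatment (16.4 ± 4.78, n = 2). In Cd4Cre the share went from 51.0% and 72.2% to 21.8%, in Bcl6 KO from 43.2% and 62.4% to 16.01%, and in the libraries labelled Prdm1 KO from 26.5% and 45.2% to 22.8%. The mean of the 4 within-genotype differences was -33.6 percentage points (exact two-sided permutation test within genotype, p = 0.00617, the smallest that the arrangements allow). Within replicate numbers the 5 treated-minus-untreated pairs were -34.5, -54.8, -29.2, -27.2 and -3.69 points, the last from the Prdm1 KO pair. Permuting within genotype and replicate number gave -26.2 points with an exact two-sided p of 0.0625, the smallest that its 32 arrangements allow. The CD8 T-like share of T cells differed by 8.13 points, which did not pass the same test (exact permutation p = 0.253). With untreated and treated libraries together, the Treg-like share differed from Cd4Cre by -16.8 points in Prdm1 KO and -7.77 points in Bcl6 KO. Their exact two-sided permutation p-values were 0.333 and 0.5, and 0.167 is the smallest that 12 arrangements allow. In the libraries labelled Prdm1 KO, 9.06% to 20.5% of regulatory lineage cells had other leading genes and were left out of the class. Elsewhere this was 0.131% to 1.20%. Il2ra, a Treg marker in that check, is lower in the libraries labelled Prdm1 KO. Batf3 and MHC class II genes, markers of other types, are higher there. With all sub-clusters of a clear lineage, an alternative chosen after seeing the data, the Prdm1 KO difference was -14.3 points. The Prdm1 KO difference was -8.17 points without untreated Cd4Cre replicate 2 and -8.89 without untreated Prdm1 KO replicate 1. Leaving out the treated Cd4Cre library or the treated Prdm1 KO library gave -25.7 points. The Bcl6 KO difference was -1.41 points without untreated Cd4Cre replicate 2, -1.98 without untreated Bcl6 KO replicate 1, -13.5 without untreated Cd4Cre replicate 1 and -13.0 without untreated Bcl6 KO replicate 2.

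**Figure D2:**
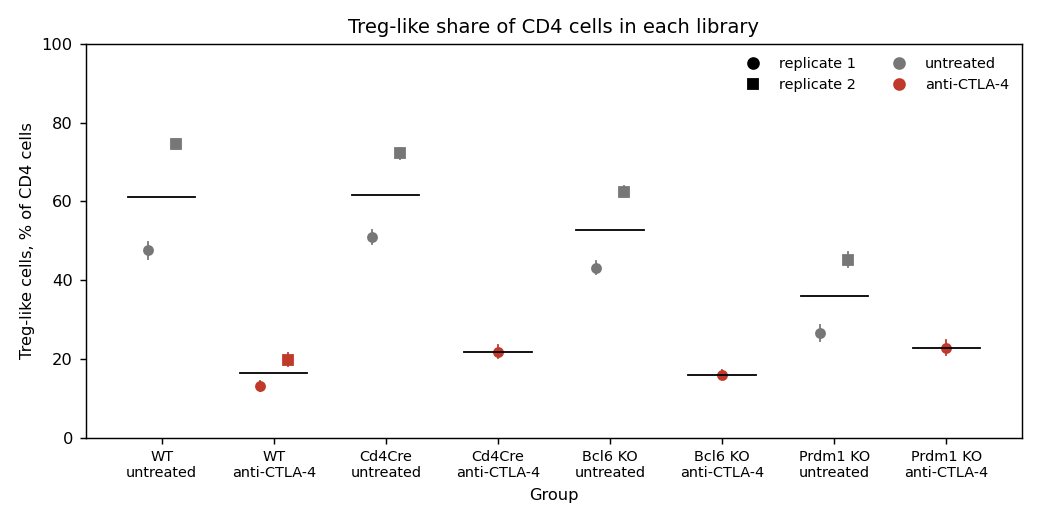
Treg-like cells as a percentage of CD4 cells in each library, with the 95% Wilson interval as a bar, replicate 1 as circles, replicate 2 as squares and a line at the group mean. The treated libraries stand between 13.1% and 22.8% and the untreated ones between 26.5% and 74.6%.

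In WT CD4 Tconv-like cells, anti-CTLA-4 went with more cell cycle transcript and less Il10, and the cytotoxic list was not called. This comparison asks what the antibody changes in conventional CD4 cells. Ccnb2, a mitotic cyclin, stood at 58.3 ± 6.00 CPM against 12.9 ± 0.232 (n = 2 and 2), and Birc5, a chromosomal passenger protein, at 119 ± 31.9 against 27.9 ± 1.72. Il10, a regulatory cytokine, stood at 0.555 ± 0.277 CPM against 17.0 ± 5.39. Gzmb, the granzyme of killer cells, stood at 799.6 ± 74.8 CPM against 638 ± 96.6. With edgeR, 0 of 12529 genes passed an adjusted p of 0.05, 313 had an unadjusted p under 0.05, and DESeq2 called 17 rises and 2 falls. In the blocked fit 5 genes rose and 1 fell, namely Ccnb2 (log2 change 2.17, adjusted p = 0.0356), Birc5 (2.09), Ccna2 (1.67), Cdca8 (2.18), Ube2c (1.65) and Il10 (-4.81), the last 5 at an adjusted p of 0.0487. Within replicate 1 and replicate 2 the log2 ratio was 2.04 and 2.21 for Ccnb2 and -3.45 and -4.63 for Il10.

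As a group, the cell cycle genes of WT CD4 Tconv-like cells rose after anti-CTLA-4. Of 26 measured, 0 passed over all genes tested and 20 adjusted over the list alone, and their median log2 change was 1.52 (camera adjusted p = 2.3e-72). The adjusted p was 0.0467 with an estimated correlation, and 0.16 with an estimated correlation in the blocked fit. Mki67 (1.95) and Top2a (1.46) lay on the same side without passing. Cycling cells, those with a UMI of at least 3 cycling markers, were 9.65% and 23.8% of the class in treated and 4.92% and 5.86% in untreated WT libraries. This share depends on depth, and untreated WT replicate 2 had a median of 1735 UMIs per cell against 3175.5 in the treated one. With at least 2000 UMIs per cell the shares were 11.1% and 28.8% against 5.28% and 11.8%. The Treg list fell (21 measured, 1 adjusted over the list alone, median -0.44, camera adjusted p = 4.0e-08, adjusted p = 0.0714 with an estimated correlation). Foxp3, its defining factor, stood at 5.68 ± 3.12 against 18.5 ± 8.96 CPM. The class was named by Foxp3 in under 15% of cells. In the same libraries Treg-like cells went from 47.6% and 74.6% to 13.1% and 19.8% of CD4 cells. For this list and Foxp3, Treg-like RNA or cells within the class are not separated from a change in conventional cells. The naive and memory list fell (15 measured, 1 adjusted over the list alone, median -0.57, camera adjusted p = 1.2e-06, adjusted p = 0.22 with an estimated correlation), with Ccr7, a lymph node homing receptor, at -1.64 and Tcf7 at -0.57. A naive-like cluster held 4.01% and 3.20% of the class in treated and 11.0% and 4.80% in untreated WT libraries, which is not separated from changes within cells. The interferon response list (27 measured, median -0.40, adjusted p = 0.329 with an estimated correlation) and the Tfh list (17 measured, median -0.19, adjusted p = 0.214 with an estimated correlation) fell by camera. Glycolysis (17 measured, median 0.37) and oxidative phosphorylation (21 measured, median 0.37) rose by camera, at an adjusted p of 0.487 and 0.513 with an estimated correlation.

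Of the 22 measured cytotoxic genes in WT CD4 Tconv-like cells, 0 passed over all genes tested and 1 passed adjusted over the list alone (median 0.03, camera adjusted p = 0.176). CD4 sub-clusters led by markers of another type were left out, and Nkg7, Gzmk and Gzma are among the CD8 and NK markers. This took 12.9% and 10.5% of conventional lineage cells in treated and 7.80% and 6.55% in untreated WT libraries. The lists were not tested with these cells, which limits cytotoxic genes in each comparison of this class. Gzmc stood at 135 ± 41.6 CPM against 18.7 ± 0.840 (log2 2.85, edgeR adjusted p = 0.631, DESeq2 adjusted p = 0.000831), with ratios of 3.06 and 2.51 within replicates. The log2 changes of Prf1, the pore-forming protein, Gzma and Gzmk were 0.30, 1.05 and -0.21. Those of Gzmd, Gzme and Gzmf were -0.27, -0.13 and 0.71. Ifng, the main Th1 cytokine, stood at 789.7 ± 63.9 CPM against 329.9 ± 284 (ratios 0.65 and 2.52 within replicates), Tnf at a log2 change of 0.43 and the Th1 factor Tbx21 at 0.14. Eomes, Il2 and Il21 stood at -0.28, 0.11 and 0.49, and Prdm1 and Bcl6 at 0.27 and 0.09. The receptors Pdcd1, Ctla4 and Il2ra stood at -0.74, -0.37 and 0.40. Zc3h12a, which encodes the RNase Regnase-1, stood at 58.6 ± 2.42 CPM against 66.3 ± 4.00, and the post-transcriptional regulator list was not called (28 measured, median 0.01, camera adjusted p = 0.809). The Th1, Th2 and Th17, inhibitory receptor, cytokine, IL-2 and STAT5, immediate early and tissue residency lists were not called either, at medians of 0.14, -0.07, -0.17, 0.07, 0.09, 0.09 and -0.03. The cytokine list's mean of -0.20 and its test pointed down while its median was positive. Among marker lists of cell types, the median was 1.75 for cycling cells, -0.37 for Treg, -0.03 for conventional CD4, -0.18 for CD8, -0.40 for NK or innate lymphoid, -0.62 for γδ T, 0.01 for B or plasma, -0.42 for myeloid, -0.35 for dendritic, -0.24 for endothelial and -3.41 for erythroid or platelet genes, with 0 called. Tumour and fibroblast markers also moved with this comparison, at a median of -3.79 over 14 genes with 0 called, and summed to 469 CPM in untreated WT replicate 2 against 48.6 to 60.8 CPM in the other WT libraries. In simulated data of this size 1% of genes changed 4-fold were recovered.

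**Figure D3:**
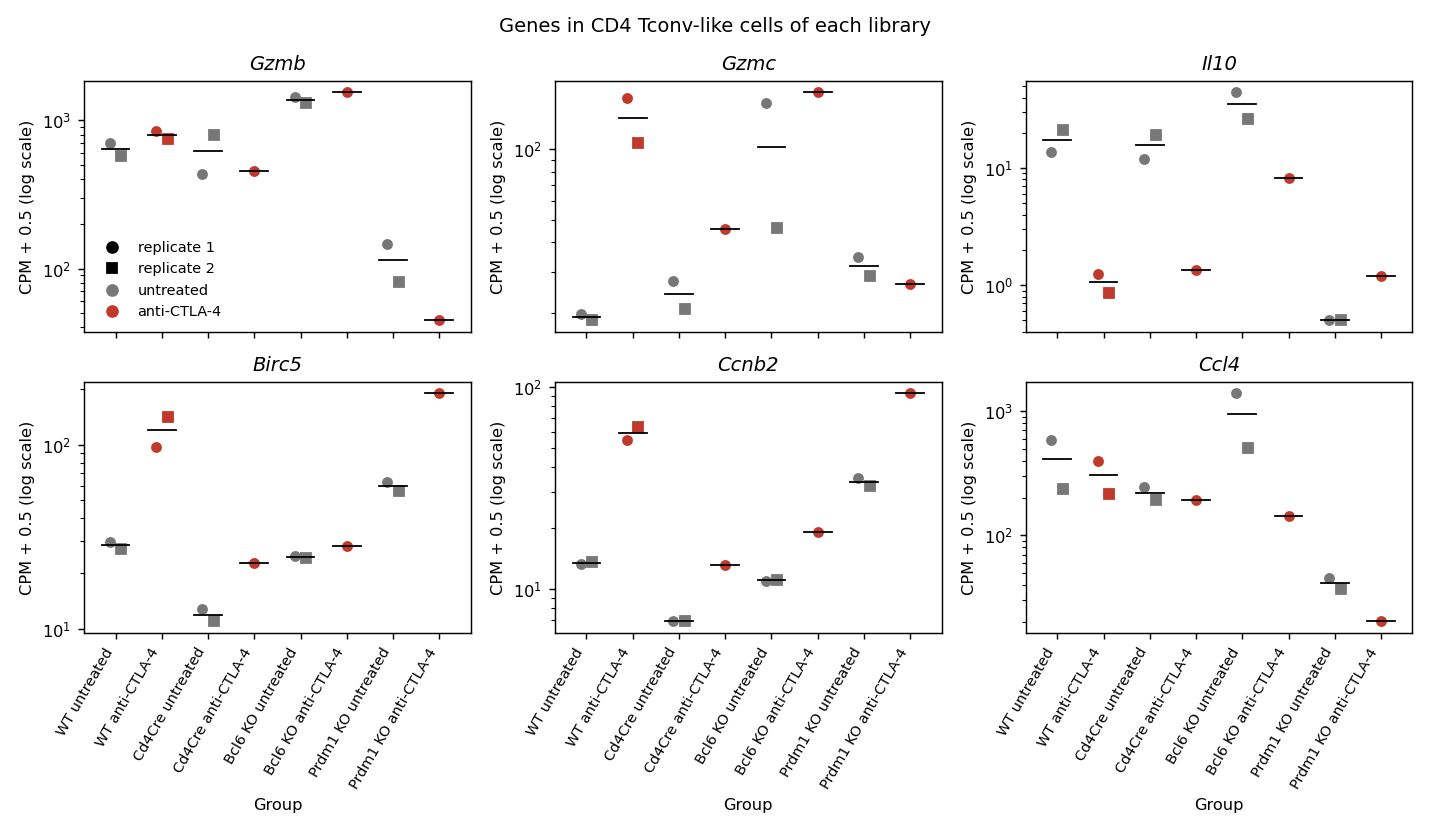
CPM plus 0.5 (log scale) of 6 genes in CD4 Tconv-like cells of each library, with replicate 1 as circles, replicate 2 as squares and a line at the group mean. Ccnb2 stands at 58.3 ± 6.00 CPM in treated WT and 12.9 ± 0.232 CPM in untreated WT libraries, and Il10 is at 0 in both untreated libraries labelled Prdm1 KO.

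Over the 4 genotypes the same contrast in CD4 Tconv-like cells again showed higher mitotic transcript after anti-CTLA-4. This comparison asks which changes hold on average over genotypes. Ccnb2 stood at 48.0 ± 32.8 CPM in 5 treated and 15.8 ± 11.1 in 8 untreated libraries, with 5 of 5 pairs in that direction. Foxp3 stood at 6.79 ± 4.27 against 19.3 ± 6.89 CPM (5 of 5 pairs), with the limit from Treg-like RNA or cells given for WT. Gzmb stood at 728 ± 553 against 686 ± 494 CPM (log2 -0.33, 1 of 5 pairs), where the library means and the fit, which weights genotypes equally, point opposite ways. With edgeR 0 genes passed, 541 had an unadjusted p under 0.05, and DESeq2 called 17 rises and 18 falls. The blocked fit had 5 rises and 0 falls. The rises were Ccnb2 (log2 1.37, adjusted p = 0.0188), Birc5 (1.24), Ccna2 (1.07), Ube2c (1.17) and Cdca3 (1.17). The cell cycle list rose (26 measured, 0 passed over all genes tested and 21 adjusted over the list alone, median 0.88, camera adjusted p = 5.1e-54). Its adjusted p was 0.0467 with an estimated correlation and 0.177 with that in the blocked fit. The cycling share of the class was higher after treatment in 5 of 5 pairs, 4.92% to 9.65% and 5.86% to 23.8% in WT, 3.52% to 6.34% in Cd4Cre, 3.35% to 5.13% in Bcl6 KO and 8.10% to 14.2% in Prdm1 KO. With at least 2000 UMIs per cell the WT replicate 2 pair was 11.8% to 28.8%, and the share still rose in the other pairs. The naive and memory list fell (15 measured, 2 adjusted over the list alone, median -0.71, adjusted p = 0.214 with an estimated correlation), with Ccr7 at -1.13 and Tcf7 at -0.49. A naive-like cluster went from 11.0% to 4.01% and 4.80% to 3.20% of the class in WT, 4.47% to 1.01% in Bcl6 KO and 3.18% to 2.20% in Prdm1 KO. In Cd4Cre it went from 4.27% to 5.06%. Such shifts are not separated from changes within cells. The interferon, Treg and Tfh lists also fell by camera (medians -0.35, -0.27 and -0.22). Their adjusted p was 0.368, 0.23 and 0.22 with an estimated correlation. Glycolysis, oxidative phosphorylation and the IL-2 and STAT5 list rose by camera (medians 0.37, 0.27 and 0.11). Their adjusted p was 0.403, 0.505 and 0.658 with an estimated correlation, and the last lost its camera call in the blocked fit (adjusted p = 0.662). The cytotoxic list was not called (median 0.05, camera adjusted p = 0.11), with the limit from left-out cells given for WT. Among core genes Gzmc stood at a log2 change of 1.07, Prf1 at -0.22, Gzma at 0.07, Gzmk at 0.17, Ifng at 0.23, Tnf at 0.30 and Tbx21 at 0.17. Eomes, Il2, Il21, Pdcd1, Ctla4 and Il2ra stood at -0.09, 0.32, -0.31, 0.01, -0.08 and -0.05, and Prdm1, Bcl6 and Zc3h12a at 0.05, -0.64 and 0.25. The tumour and fibroblast marker median was -3.21 with 0 of 14 called. Of the 5 treated libraries 1 is a replicate 2 library, so this contrast partly follows the Cell Ranger version. In 5 untreated and treated pairs, an alternative chosen after seeing the data, 1 gene passed, the immediate early gene Ier3 (log2 0.97 in the full fit).

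In untreated CD4 Tconv-like cells of the libraries labelled Prdm1 KO, Gzmb, Il10 and the chemokines Ccl3 and Ccl4 were lower than in Cd4Cre, and mitotic genes were higher. This comparison asks what the Prdm1 deletion named in the labels changes in conventional CD4 cells. Treg-like RNA or cells within the class limit these falls, as given with the lists below. Gzmb stood at 114 ± 45.8 CPM against 617 ± 256 (n = 2 and 2), with log2 ratios of -1.57 and -3.29 within replicates. Il10 had 0 UMIs in both labelled libraries against 204, at least 21.4-fold lower against a floor of 3 counts per library. Ccl4 stood at 40.6 ± 5.88 CPM against 218 ± 36.7 (ratios -2.44 and -2.39) and Prdm1 itself at 115 ± 21.7 against 21.7 ± 4.76. With edgeR 0 of 12529 genes passed, 413 had an unadjusted p under 0.05, and DESeq2 called 29 rises and 6 falls. In the blocked fit 22 rose and 7 fell. The falls held Gzmb (log2 -2.47, adjusted p = 0.0373), Ccl3 (-3.03), Ccl4 (-2.44), Il10 (adjusted p = 0.023) and Neb (-3.06). The rises held Prdm1 (2.44, adjusted p = 0.0108), the cytokine Lif (2.38), the OX40 ligand Tnfsf4 (2.42), the tubulin Tuba8 (4.47) and the AP-1 factor Batf3, with 105 UMIs against 0, at least 31.7-fold higher by the same floor. Mitotic genes among them were Ube2c (2.92), Ccnb2 (2.37), Birc5 (2.37), Plk1 (2.33) and Ccna2 (1.84).

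By list, the cell cycle genes of these cells rose (26 measured, 0 passed over all genes tested and 20 adjusted over the list alone, median 1.70, camera adjusted p = 1.1e-72, adjusted p = 0.0467 with an estimated correlation). The blocked fit had 9 rises in this list, and its adjusted p was 0.16 with an estimated correlation. The interferon response list fell (27 measured, median -0.64, adjusted p = 0.22 with an estimated correlation), with Isg15 at -0.63 and Ifit3 at -0.80. The Treg list fell (21 measured, 1 adjusted over the list alone, median -0.43, adjusted p = 0.0685 with an estimated correlation), as did the Tfh list (17 measured, median -0.43, adjusted p = 0.0685 with an estimated correlation) and the immediate early list (20 measured, median -0.31, adjusted p = 0.658 with an estimated correlation), whose camera call was lost in the blocked fit (adjusted p = 0.162). Th2 and Th17 genes (14 measured, median 0.47) and oxidative phosphorylation (21 measured, median 0.24) rose by camera, at an adjusted p of 0.397 and 0.664 with an estimated correlation. The cytotoxic list was not called one way (22 measured, 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.2). Camera called it up in the blocked fit (adjusted p = 0.0448, or adjusted p = 0.54 with an estimated correlation) while Gzmb fell. Prf1, Gzma, Gzmc and Gzmk stood at 0.04, -0.22, 0.40 and -0.73, with Prf1 ratios of -1.29 and 1.27 within replicates. Ifng stood at 1.19 and Tnf at 0.45, and their ratios within replicates had opposite signs (1.67 and -0.71, 0.89 and -0.56). Tbx21, Eomes, Il2, Il21 and Tcf7 stood at 0.17, 0.52, 1.68, -0.73 and 0.01. Pdcd1, Ctla4, Il2ra, Foxp3, Bcl6 and Zc3h12a stood at -0.56, -0.39, -0.27, -0.99, -0.29 and 0.01. Treg-like RNA or cells within the class limit the Treg list and Foxp3 here as in WT. They also limit the falls of Gzmb, Il10, Ccl3 and Ccl4, which stood lower in Treg-like cells of these libraries too. The same holds for Neb, a leading gene of a Treg-like cluster. Gzmb and Il10 are weighed further below, and Ccl3, Ccl4 and Neb were not tested for this. The make-up of the class differed too. A cluster of low UMI counts held 1.97% and 17.5% of the cells of the labelled libraries against 28.2% and 22.2% in Cd4Cre, and cycling cells were 8.10% and 5.12% against 3.52% and 3.28%. A shift between such cells and a change within them are not separated here. Markers of other cell types moved with these groups, at medians of 1.48 for tumour and fibroblast, 1.19 for B or plasma, 1.14 for dendritic, 0.94 for NK or innate lymphoid and 0.83 for CD8 genes, with 0 called. In simulated data of this size 1% of genes changed 4-fold were recovered.

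In untreated CD4 Tconv-like cells of the libraries labelled Bcl6 KO, Gzmb and Gzmc stood higher and the follicular helper genes Cxcr5 and Tox2 lower than in Cd4Cre. This comparison asks what the Bcl6 deletion named in the labels changes in the same cell class. Gzmb stood at 1377 ± 84.5 CPM against 617 ± 256 (n = 2 and 2, log2 ratios of 1.72 and 0.72 within replicates). Cxcr5, the chemokine receptor that guides T cells to follicles, stood at 0.668 ± 0.384 against 9.47 ± 3.44 CPM. As a list, cytotoxic genes rose (22 measured, 0 passed over all genes tested and 3 adjusted over the list alone, median 0.54, camera adjusted p = 6.0e-09, adjusted p = 0.22 with an estimated correlation). Nkg7, a granule membrane protein, stood at 1326 ± 419 against 537 ± 78.8 CPM, Gzmc at 101 ± 78.7 against 23.6 ± 4.77 and Gzmk at 12.7 ± 0.320 against 38.8 ± 9.38. Gzmd, Gzme and Gzmf stood at log2 changes of 3.09, 3.34 and 3.97, and Prf1 and Gzma at 1.04 and 0.25. The Tfh list fell (17 measured, 2 adjusted over the list alone, median -0.24, camera adjusted p = 2.2e-06, adjusted p = 0.0467 with an estimated correlation). In the blocked fit that was an adjusted p of 0.16 with an estimated correlation. Its members Tox2, Slamf6 and Sh2d1a stood at -3.57, -1.07 and -0.62, and Izumo1r at 0.48. The cell cycle list rose (2 adjusted over the list alone, median 0.51, adjusted p = 0.214 with an estimated correlation), as did the cytokine list (median 0.27, adjusted p = 0.491 with an estimated correlation), with Ccl3 at 2.92 and Ccl4 at 2.11. The share of cycling cells was not higher, at 3.35% and 2.04% against 3.52% and 3.28% in Cd4Cre. With at least 2000 UMIs per cell it was 3.76% and 3.75% against 4.03% and 3.74%. Oxidative phosphorylation and glycolysis rose and the interferon list fell by camera (medians 0.23, 0.24 and -0.14). Their adjusted p was 0.596, 0.596 and 0.664 with an estimated correlation. With edgeR 0 of 12529 genes passed, 186 had an unadjusted p under 0.05, and DESeq2 called 3 rises and 4 falls. Of the genes called in the blocked fit, Scg5 rose (log2 4.90, adjusted p = 0.0471) and Dthd1 fell (-3.46, adjusted p = 0.0471). Ifng stood at 568 ± 302 against 155 ± 62.3 CPM. Tnf, Tbx21, Eomes, Il2, Il21 and Tcf7 stood at log2 changes of 0.05, 0.14, -1.54, 1.53, 0.03 and -0.45. Pdcd1, Ctla4, Il2ra, Foxp3, Prdm1, Bcl6 and Zc3h12a stood at 0.03, 0.05, -0.18, -0.65, 0.52, 0.41 and 0.17. The class differed in make-up, with a naive-like cluster at 4.47% and 29.5% against 4.27% and 9.54% in Cd4Cre and a cluster of low UMI counts at 16.9% and 3.97% against 28.2% and 22.2%, and these shifts are not separated from changes within cells. The tumour and fibroblast marker median was 2.21 over 14 genes with 0 called. In simulated data of this size 6% of genes changed 4-fold were recovered.

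Whether anti-CTLA-4 acted differently by genotype was tested in CD4 Tconv-like cells as a difference of effects. By edgeR as reported, 0 genes had a difference from Cd4Cre that passed, for Prdm1 KO or for Bcl6 KO. At an unadjusted p under 0.05 there were 48 for Prdm1 KO and 55 for Bcl6 KO. DESeq2 called 0 for Prdm1 KO and 1 for Bcl6 KO. In the libraries labelled Prdm1 KO the core genes with the largest differences were Ifng (log2 -3.56 ± 1.76, SE), Gzma (-2.82 ± 1.39) and Foxp3 (2.71 ± 0.86). In Bcl6 KO they were Ifng (-2.52 ± 1.72) and Il21 (-1.60 ± 1.15). Treg-like RNA or cells within the class limit the Foxp3 difference too. The Treg-like share of CD4 cells changed by -29.2 points in the Cd4Cre pair and -3.69 points in the Prdm1 KO pair. For Gzmb the differences were -0.93 ± 0.65 and 0.60 ± 0.65. Over both contrasts the other core genes stayed between -2.33 (Il2, Prdm1 KO) and 0.96 (Ctla4, Prdm1 KO). Camera called 12 of 16 lists for Prdm1 KO and 6 for Bcl6 KO, and 0 with an estimated correlation. Each of these contrasts rests on 1 treated library per genotype, assumed to vary like the other groups.

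In Treg-like cells, Lag3, Ccr8, Il10, Ccl3 and Ccl4 fell after anti-CTLA-4, and Tcf7 and Slamf6 rose. This comparison asks what marks the regulatory cells that remain after treatment. Conventional cells outnumbered Treg-like cells more strongly in treated libraries. For the rises, conventional RNA or cells within the class were not tested and are not separated from a change in regulatory cells. Averaged over 4 genotypes, Lag3, an inhibitory receptor, stood at 42.0 ± 23.0 CPM in 5 treated against 396 ± 263 in 8 untreated libraries (log2 -2.99, adjusted p = 0.012). Ccr8, a receptor of tumour Treg cells, stood at 75.5 ± 24.6 against 276 ± 90.4 CPM (-1.92), and Tcf7, a factor of resting and memory cells, at 78.7 ± 42.2 against 35.7 ± 29.8 (1.24). With edgeR 13 of 11522 genes rose and 98 fell. The 5 pairs gave 624 rises and 718 falls and the replicate 1 libraries 254 and 444, both alternatives chosen after seeing the data. Of 18 inhibitory receptor and exhaustion genes 0 rose and 4 fell (7 adjusted over the list alone), namely Lag3, Havcr2 (-1.81), Tigit (-1.12) and Entpd1 (-1.35). The list fell at a camera adjusted p of 3.7e-05, or adjusted p = 0.0494 with an estimated correlation and 0.115 with that in the blocked fit. Of 21 Treg genes 4 fell (12 adjusted over the list alone, median -0.39, adjusted p = 0.0944 with an estimated correlation), namely Ccr8, Klrg1 (-1.21), Tigit and Il10 (-3.75). Foxp3 stood at 0.28 and Ctla4 at -0.07, and neither passed. Of 20 cytokines and chemokines 4 fell (5 adjusted over the list alone, adjusted p = 0.366 with an estimated correlation), namely Ccl4 (-3.82), Ccl3 (-3.11), Csf1 (-1.33) and Il10. Of 14 naive and memory genes 2 rose (6 adjusted over the list alone), Tcf7 and Slamf6 (0.96), at a camera adjusted p of 6.3e-05, or adjusted p = 0.0494 with an estimated correlation and 0.0915 with that in the blocked fit. Of 17 residency genes 2 rose, Itgb1 (1.19) and Klf3 (1.27) (8 adjusted over the list alone, adjusted p = 0.366 with an estimated correlation). Th1 genes were not called as a list (17 measured, 4 adjusted over the list alone), while Tbx21 (-1.14) and Il12rb2 (-1.75) fell, nor were cytotoxic genes (18 measured, 5 adjusted over the list alone), while Cst7 (-1.60) and Fasl (-1.45) fell. Ccr6 rose (1.27) in the Th2 and Th17 list, whose median (-0.13) and mean pointed down while camera called it up (adjusted p = 0.0347, or adjusted p = 0.192 with an estimated correlation).

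The remaining named genes of this Treg-like contrast were rises in Rflnb (2.06), Nebl (1.61), Prg4 (1.57), Gbp2b (1.56) and Serpinb1a (1.52). Rflnb, Nebl, Klf3, Serpinb1a and Tcf7 are among the leading genes of clusters that held CD4 Tconv-like cells. The limit from conventional RNA or cells therefore bears on them directly. Kcna4, a potassium channel gene, fell from 4.35 ± 1.83 to 0.491 ± 0.930 CPM. Fcrl6, Mpped2, Adora2b and Slc4a11 fell from 3.76, 3.16, 3.68 and 3.76 CPM to 0.0855, 0.0636, 0.380 and 0.235, with 1, 1, 3 and 3 UMIs in all treated libraries. All 5 pairs of one genotype and replicate number shared the direction of each named gene that passed, except Gbp2b with 4 of 5. The blocked fit had 43 rises and 147 falls with 107 of the 111 genes among them, and Adora2b (adjusted p = 0.0527) and Slc4a11 (adjusted p = 0.0626) did not. The Tfh, cell cycle, oxidative phosphorylation and immediate early lists rose and the interferon list fell by camera, at medians of 0.27, 0.25, 0.15, 0.09 and -0.40. Their adjusted p was 0.0874, 0.383, 0.576, 0.513 and 0.411 with an estimated correlation. In that fit camera lost the residency (adjusted p = 0.0777), cytokine (adjusted p = 0.106) and immediate early (adjusted p = 0.144) lists and called glycolysis down (median -0.21, adjusted p = 0.0406, or adjusted p = 0.606 with an estimated correlation). The count of 111 rested on single libraries. It was 14 without untreated Cd4Cre replicate 2 and 38 without replicate 1, 15 without untreated Bcl6 KO replicate 2 and 27 without replicate 1. It was 34 without untreated Prdm1 KO replicate 2 and 25 without replicate 1. Without the treated Cd4Cre library it was 36, without the treated Bcl6 KO library 43, and without treated WT replicate 1 or 2 it was 61 or 68. Classes set by UMI gates gave 21, all among the 111. A cluster led by interferon genes and Il10 held 0.438% to 6.06% of the class in treated and 1.63% to 11.6% in untreated libraries. Within pairs it went from 11.6% to 4.53% and 5.86% to 1.82% in WT and from 6.71% to 6.06% in Cd4Cre. In Bcl6 KO it went from 4.41% to 1.52% and in Prdm1 KO from 5.66% to 0.438%. For Il10 and the interferon list such shifts are not separated from changes within cells. Myeloid and tumour or fibroblast marker medians moved with this contrast, at -1.60 and -3.04 with 0 of 16 called in each, and the summed tumour and fibroblast markers stood at 495 CPM in untreated WT replicate 2.

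In WT alone no single gene passed in Treg-like cells, and Lag3 and Il10 stood lower after treatment. Lag3 stood at 37.0 ± 1.96 CPM against 602 ± 355 (n = 2 and 2, log2 ratios of -4.46 and -3.29 within replicates) and Il10 at 17.1 ± 7.48 against 201 ± 16.9 (ratios -4.11 and -3.05). Gzmb stood at 2188 ± 829.7 against 6007 ± 2541, Foxp3 at 597 ± 176 against 648 ± 225 and Ctla4 at 1425 ± 114 against 1702 ± 166. With edgeR 0 genes passed, 748 had an unadjusted p under 0.05, and DESeq2 called 27 rises and 87 falls. In the blocked fit 29 rose and 71 fell, among them Lag3 (-3.93, adjusted p = 0.00683), Havcr2 (-2.25), Ccr8 (-2.15), Il10 (-3.58), Tigit (-1.65), Tcf7 (2.05) and Slamf6 (1.62). The limits from conventional RNA or cells and from shifts between clusters, given for the mean over genotypes, hold here too. The Tfh and naive and memory lists rose and the inhibitory receptor and Treg lists fell, at medians of 1.25, 0.96, -0.30 and -0.64. Adjusted over the list alone 8, 5, 7 and 11 of their genes passed, against 0 over all genes tested. For these 4 lists camera gave an adjusted p = 0.0494 with an estimated correlation, and between 0.0743 and 0.0894 with that in the blocked fit. Camera called 11 of 16 lists, or 10 in the blocked fit, where oxidative phosphorylation was lost (adjusted p = 0.0508), and 4 with an estimated correlation or 0 with that in the blocked fit. Tumour and fibroblast, myeloid and dendritic marker medians moved with this contrast, at -2.85, -1.34 and -1.18 with 0 called. Without untreated WT replicate 2 the count by edgeR was 1. In simulated data of this size 15% of genes changed 4-fold were recovered.

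**Figure D4:**
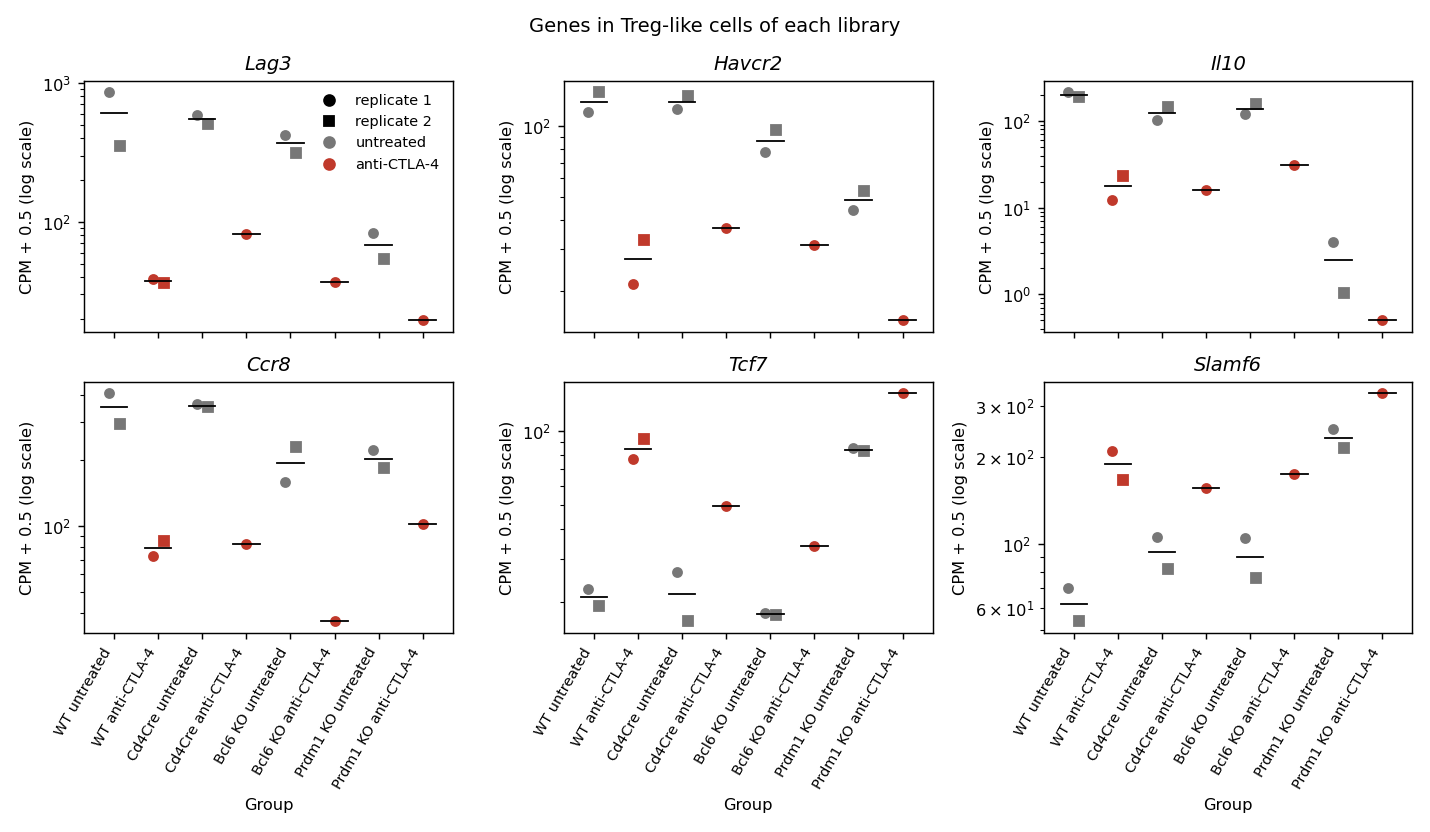
CPM plus 0.5 (log scale) of 6 genes in Treg-like cells of each library, with replicate 1 as circles, replicate 2 as squares and a line at the group mean. Over all genotypes Lag3 stands at 42.0 ± 23.0 CPM in treated and 396 ± 263 CPM in untreated libraries, and Tcf7 at 78.7 ± 42.2 and 35.7 ± 29.8 CPM.

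In the fit as reported, though not in every alternative, the highest count of called genes came from untreated Treg-like cells of the libraries labelled Prdm1 KO. There Il10 and Prf1 fell and cell cycle genes, Ccr7 and MHC class II genes rose. This comparison asks what that deletion changes in regulatory cells. Il10 stood at 2.00 ± 2.08 CPM against 124 ± 31.8 in Cd4Cre (n = 2 and 2, log2 -6.01, adjusted p = 0.00711). Ccr7 stood at 346 ± 90.8 against 25.4 ± 1.77 (3.77) and Lif at 51.6 ± 4.71 against 0.757 ± 0.218 (6.09, adjusted p = 0.00214). Gzmb stood at 205 ± 254 against 5887 ± 474 (log2 ratios of -3.85 and -7.90 within replicates) and missed the threshold (adjusted p = 0.0545), which it passed in the blocked fit (-5.31, adjusted p = 0.00838). With edgeR 264 of 11522 genes rose and 165 fell. The make-up of the class differed too. Cycling cells were 23.1% and 23.6% of it in the labelled libraries against 5.08% and 4.89% in Cd4Cre. A cluster led by cycle genes, Batf3 and Cd74 held 12.6% and 16.7% against 2.18% and 2.15%, and a cluster led by interferon genes and Il10 held 5.66% and 1.63% against 6.71% and 10.3%. A cluster of low UMI counts held 5.66% and 15.7% against 27.8% and 19.1%. The changes are those of the class as a whole, with shifts between such cells included.

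In these Treg-like cells the cytotoxic, Treg, interferon response, Th1, residency and IL-2 and STAT5 lists fell by camera, while the inhibitory receptor and cytokine lists were not called. Of 18 cytotoxic genes 3 fell (7 adjusted over the list alone, adjusted p = 0.237 with an estimated correlation), namely Prf1 (-3.63), Nkg7 (-2.11) and Gzma (-1.77). Of 21 Treg genes 5 fell (11 adjusted over the list alone, median -0.81, camera adjusted p = 4.3e-08, adjusted p = 0.0494 with an estimated correlation and 0.0743 with that in the blocked fit). They were Il10, Il2ra (353 ± 37.0 against 1254 ± 168 CPM), Lrrc32 (-1.57), Tnfrsf9 (-1.41) and Itgae (-1.19), while Foxp3 (-0.48), Ikzf2 (-0.36) and Ctla4 (-0.80) did not pass, although Ctla4 did in the blocked fit (adjusted p = 0.0483). Of 18 inhibitory receptor genes 4 fell (10 adjusted over the list alone), with Entpd1 (-3.24), Lag3 (-3.01) and Havcr2 (-1.39) beside Tnfrsf9, and the list itself was not called (camera adjusted p = 0.129). Of 27 interferon response genes 10 fell (19 adjusted over the list alone, median -1.40, adjusted p = 0.158 with an estimated correlation), such as Isg15 (-1.82) and Stat2 (-1.47). The Th1 list fell with 1 member past the threshold (3 adjusted over the list alone, median -0.69, adjusted p = 0.0494 with an estimated correlation and 0.0894 with that in the blocked fit). Of 20 cytokines and chemokines 3 fell and 1 rose (7 adjusted over the list alone, list not called), with Ccl3 (-4.04) and Ccl4 (-3.73) beside Il10, and Lif up. Of 17 residency genes 3 fell, Ccr2 (-3.70) and Itgae among them, and Ccr7 rose (8 adjusted over the list alone, adjusted p = 0.475 with an estimated correlation). In the IL-2 and STAT5 list 2 fell, Socs2 (-2.13) and Il2ra (10 adjusted over the list alone, adjusted p = 0.394 with an estimated correlation).

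The cell cycle, naive and memory, Th2 and Th17 and oxidative phosphorylation lists rose by camera in the same cells. Of 26 cell cycle genes 20 rose (24 adjusted over the list alone, median 2.66, camera adjusted p = 1.2e-51), such as Birc5 (3.53), Ccnb2 (3.39) and Top2a (2.17). That list's adjusted p was 0.0494 with an estimated correlation and 0.0743 with that in the blocked fit. Of 14 naive and memory genes 4 rose (4 adjusted over the list alone, adjusted p = 0.0944 with an estimated correlation), namely Ccr7, Id3 (3.12), Tcf7 (1.99) and Slamf6 (1.32). Of 15 Tfh genes 4 rose and 1 fell (11 adjusted over the list alone, list not called), with Cxcr5 (3.27), Il4 (3.87), Sh2d1a (1.59) and Slamf6 up and Izumo1r (-2.18) down. In the Th2 and Th17 list Il4 and Ccr6 (1.68) rose (4 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), and oxidative phosphorylation rose as a list (median 0.39, adjusted p = 0.57 with an estimated correlation). Glycolysis, with Slc2a3 down (-1.34), the post-transcriptional regulators and the immediate early list were not called, at medians of -0.01, -0.02 and -0.28. MHC class II transcripts, usually a mark of antigen-presenting cells, rose. H2-Aa stood at 175 ± 15.7 CPM against 5.01 ± 0.644 (5.12), H2-Ab1 at 4.09, H2-Eb1 at 4.44 and their chaperone Cd74 at 2.51. The marker median was 4.09 for dendritic (3 of 5 rose), 1.74 for B or plasma (2 of 7 rose) and -0.36 for myeloid genes (0 of 16 passed). The dendritic risers were H2-Ab1, H2-Eb1 and Batf3, and the B or plasma risers were Cd74 and H2-Aa. These are the same genes again, so the 2 lists are not separate evidence of other cells. Prdm1 rose (2.20), and Bcl6 stood at 32.5 ± 25.3 against 5.82 ± 3.99 CPM, called in the blocked fit (adjusted p = 0.0012). Batf3 rose, with 798 UMIs against 2, a ratio of 1361 (95% counting interval 375 to 11254), as did Tmem121 (60 against 2, ratio 102, 27.1 to 864) and Oaf (5.23). Ky fell (1 UMI against 283, ratio 83.0, 14.8 to 3289.6), as did Slfn4 and Calca, with 0 UMIs against 158 and 93, at least 7.15-fold and 4.65-fold lower against a floor of 3 counts per library.

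This count of 429 in Treg-like cells was 1304 in the blocked fit (all 429 among them) and 834 with DESeq2. It was 3 without untreated Cd4Cre replicate 1, 1 without Cd4Cre replicate 2, 35 without Prdm1 KO replicate 1 and 42 without Prdm1 KO replicate 2. Without cycling cells, an alternative chosen after seeing the data, 30 rose and 30 fell, all among the 429, and Cdk1 changed sign (log2 -0.54).

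**Figure D5:**
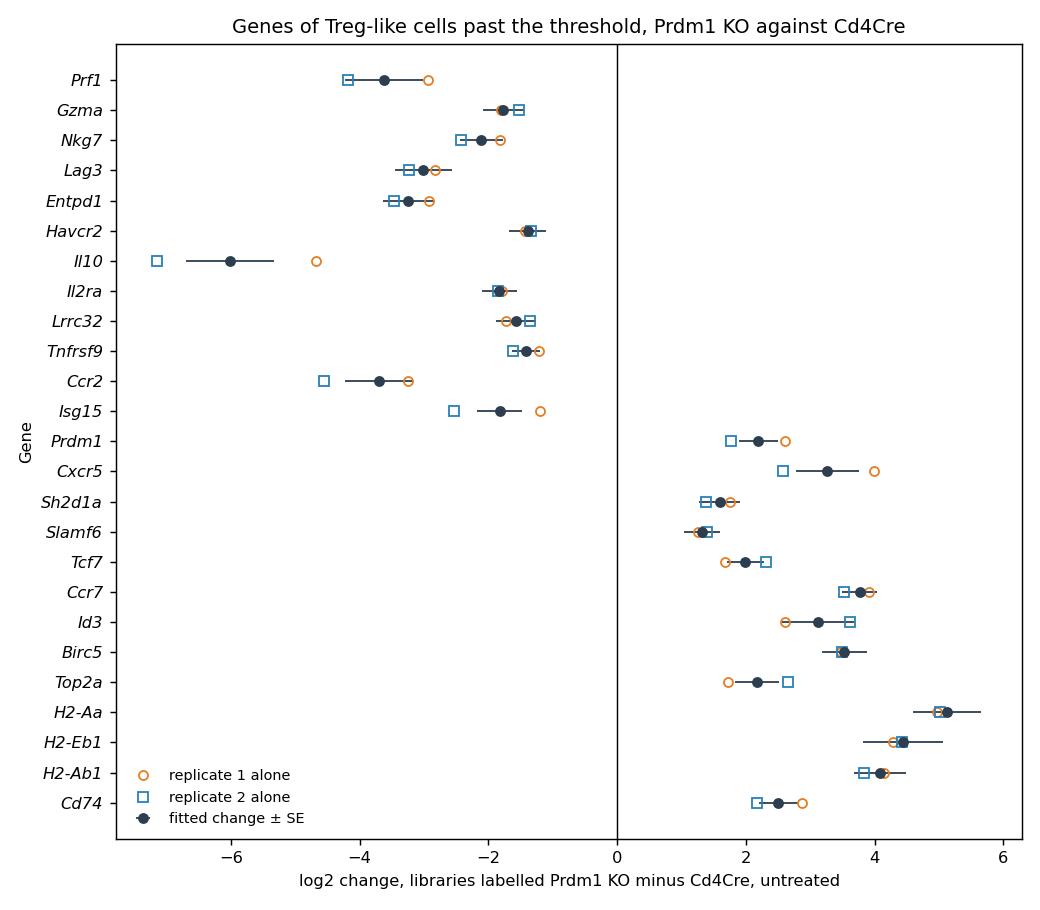
Log2 change of 25 genes in untreated Treg-like cells, libraries labelled Prdm1 KO minus Cd4Cre, as the fitted change with its standard error and as the ratio within replicate 1 and replicate 2. Il10 stands at -6.01 and H2-Aa at 5.12.

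In untreated Treg-like cells of the libraries labelled Bcl6 KO no gene passed the threshold (0 of 11522 by edgeR, 108 at an unadjusted p under 0.05, 0 by DESeq2, 0 in the blocked fit). Gzmb stood at 7058 ± 258 CPM against 5887 ± 474 in Cd4Cre (n = 2 and 2), Foxp3 at 599 ± 216 against 526 ± 173, Prdm1 at 99.8 ± 6.67 against 101 ± 19.8 and Bcl6 at 10.4 ± 6.49 against 5.82 ± 3.99. The cell cycle list rose (26 measured, 3 adjusted over the list alone, median 0.65, camera adjusted p = 6.7e-23, adjusted p = 0.0537 with an estimated correlation). The IL-2 and STAT5 and oxidative phosphorylation lists rose and the interferon, inhibitory receptor and Tfh lists fell by camera, at medians of 0.22, 0.21, -0.28, -0.17 and -0.05. Their adjusted p was 0.383, 0.475, 0.394, 0.174 and 0.181 with an estimated correlation. The Tfh call was lost in the blocked fit (camera adjusted p = 0.0567). The tumour and fibroblast marker median was 1.44 over 16 genes and that of erythroid or platelet genes 1.73 over 2, with 0 called.

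In CD8 T-like cells, the killer cells of the infiltrate, 0 of 12781 genes passed in any of the 4 contrasts by edgeR. At an unadjusted p under 0.05 there were 206 in WT after anti-CTLA-4, 510 averaged over genotypes, 553 for Prdm1 KO and 138 for Bcl6 KO, and DESeq2 called 7, 40, 31 and 1. Averaged over genotypes the 5 pairs had 53 calls and the replicate 1 libraries 15, both alternatives chosen after seeing the data. In WT Ifng stood at 1652 ± 245 CPM after anti-CTLA-4 against 482 ± 208 (log2 ratios of 1.23 and 2.44 within replicates), Gzmb at 5285 ± 966 against 3972 ± 1669.6 and Pdcd1 at 183 ± 56.6 against 379 ± 133. The make-up of the class differed, with a cluster led by Gzmc and Prf1 at 26.2% and 20.8% after treatment against 40.3% and 35.1%, and one led by Ccl5 and Gzmk at 28.0% and 22.9% against 15.5% and 18.0%. Batf3 rose in WT in the blocked fit (log2 4.71, adjusted p = 0.041), and in that fit averaged over genotypes Ephx1, an epoxide hydrolase gene, fell (-1.65, adjusted p = 0.0234, 5 of 5 pairs). For the libraries labelled Prdm1 KO, Gzmb stood at 1117 ± 717 CPM against 3147 ± 1363 (ratios -0.43 and -2.75). Its blocked fit called 6 genes, and Batf3 (5.65), Tuba8 (3.16) and Trav7n-4 (3.43) rose and Neb (-2.72), Izumo1r (-2.04) and the ectonucleotidase Entpd1 (-1.82) fell. In the libraries labelled Bcl6 KO, Gzmb stood at 5165 ± 546 against 3147 ± 1363 CPM. The cell cycle list rose in all 4 contrasts by camera (medians 0.63, 0.33, 1.32 and 0.47), at an adjusted p of 0.247, 0.337, 0.161 and 0.286 with an estimated correlation. The cycling share of the class was lower after treatment in 2 of 5 pairs, WT replicate 1 (16.4% to 14.9%) and Bcl6 KO (13.8% to 10.3%), and tumour and fibroblast marker medians stood at -3.43, -2.41, 2.02 and 1.99 with 0 called. The interferon list fell most for Prdm1 KO (27 measured, median -0.69, adjusted p = 0.222 with an estimated correlation). Camera called 11, 11, 7 and 5 of the 16 lists in the 4 contrasts, 12, 7, 4 and 5 in the blocked fit, and 0 with an estimated correlation.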

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

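Of the tests here, that of cycling cells was written before its result was seen. Those of a library swap, the Cell Ranger version, RNA of myeloid and dendritic cells and RNA of Treg-like cells were chosen after.

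In CD4 Tconv-like cells, camera called lists whose anti-CTLA-4 effect differed between genotypes. Against Cd4Cre, in the libraries labelled Prdm1 KO the median log2 difference was -0.77 for cytotoxic genes (adjusted p = 0.312 with an estimated correlation), -0.55 for Th1 (0.168), 0.80 for Tfh (0.128), -0.54 for inhibitory receptors (0.217) and 0.46 for Treg genes (0.203), each bracket with an estimated correlation. It was -0.66 for cytokines (0.465), -0.50 for IL-2 and STAT5 (0.465), -0.65 for interferon (0.312) and 0.44 for cell cycle (0.319). Glycolysis, oxidative phosphorylation and residency stood at -0.43, 0.37 and -0.36 (0.339, 0.482 and 0.312). For Bcl6 KO it was -0.37 for cytotoxic (0.339), 0.42 for Th2 and Th17 (0.339), -0.48 for naive and memory (0.438), -0.51 for inhibitory receptor (0.217), -0.23 for cytokine (0.465) and -0.49 for cell cycle genes (0.339). No list held with an estimated correlation, each contrast rests on 1 treated library per genotype, and the tumour and fibroblast marker medians stood at -5.46 and -4.40 in the same contrasts. For Prdm1 KO those of CD8, NK or innate lymphoid and dendritic markers stood at -0.80, -1.05 and -1.26, as far as the cytotoxic genes or further.

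In data outside the comparisons, cells that were not T cells made up 30.3% of untreated WT replicate 2 and 12.03% of treated WT replicate 2, although CD3+ cells were sorted, against 0.172% to 6.42% elsewhere.

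The first pattern weighed is the higher Prdm1 count in libraries labelled Prdm1 KO. A swap of 1 or 2 of them with other genotypes would put a labelled library at or under an unlabelled one, and the lowest labelled library stood 2.121 times above the highest other in CD8 T-like cells, 3.08 in CD4 Tconv-like and 2.64 in Treg-like cells. The Cell Ranger version cannot account for it within replicate 2, where both were counted with 7.0.0. There the fold over Cd4Cre was 3.98 in CD4 Tconv-like, 3.43 in Treg-like and 2.852 in CD8 T-like cells. Replicate 1 compares version 3.1.0 for Prdm1 KO with 3.0.2 for Cd4Cre, a difference that the blocked fit does not remove. An exchange of all 3 with another genotype, what raises the transcript and which exons the counted UMIs come from stay open.

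The second pattern is MHC class II transcript in Treg-like cells of these libraries. RNA or doublets of myeloid or dendritic cells would raise their other 30 markers by a predicted 1386 or 677 CPM, and these differed by -547 CPM, or -39.48% of the myeloid and -80.9% of the dendritic prediction. Without Bst2 and Ctsb, which T cells also express, the predictions were 1277 and 655 CPM over 28 markers and the observed value 36.3 CPM, and 9 B or plasma markers summed to 326 against 344 CPM in Cd4Cre. More cycling cells cannot carry it alone, since without them the median log2 difference of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 was 4.116 (edgeR adjusted p 0.0153 to 0.0333). Expression by the Treg-like cells themselves may be the source, and cells of another type that lack these markers stay open.

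The last pattern is Treg-like RNA in CD4 Tconv-like cells as a source of Il10 and Gzmb. By their Foxp3, Treg-like RNA of average make-up carried at most a median of 39.94% of the Il10 in the untreated WT and Cd4Cre libraries (24.5%, 46.3%, 33.6% and 57.8%, with upper counting bounds up to 67.1%), so it does not account for all of it. For the lower Gzmb in libraries labelled Prdm1 KO, taking such RNA away left a ratio to Cd4Cre of 0.6042 within replicate 1 (0.711 at the counting bounds) and 0.238 within replicate 2 (0.309). In replicate 1 the carried RNA and a change in the cells cannot be told apart, since at the counting bound only a small difference is left. RNA of Treg-like cells with another make-up stays open for both genes.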

How the results depend on the processing

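Alternatives chosen after seeing the data were all sub-clusters with a clear lineage, no cycling cells, the 5 pairs and the replicate 1 libraries alone. Counts are of genes called against the count as reported, and where a count moved the cause was not tested unless given.

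In CD4 Tconv-like cells the reported counts are 0. The blocked fit called 6 genes in WT, 5 for the mean of 4 genotypes, 29 for Prdm1 KO and 2 for Bcl6 KO, and DESeq2 19, 35, 35 and 7. Without a filter on low counts there were 19, 23, 31 and 9. For Prdm1 KO, doublets kept gave 3, 3 against 3 libraries 44 and a clear lineage 1, and for the mean a clear lineage gave 1 and the pairs 1. The differences of effects had 1 for Prdm1 KO and 2 for Bcl6 KO without a filter and 1 for Bcl6 KO with DESeq2. Leaving out a library gave 0 to 0 in each comparison of this class.

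In CD8 T-like cells the reported counts are 0 too. The blocked fit called 1 in WT, 1 for the mean and 6 for Prdm1 KO, and DESeq2 7, 40 and 31, with 1 for Bcl6 KO. Without a filter there were 3 for the mean and 12 for Prdm1 KO. The pairs gave 53, the replicate 1 libraries 15, and 3 against 3 libraries for Prdm1 KO 22. Leaving out a library gave 0 to 0.

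In Treg-like cells the 429 genes of Prdm1 KO became 1304 in the blocked fit, 834 with DESeq2 (421 shared), 259 with UMI gates (238 shared), 939 without a filter (393 shared), 861 with only the libraries of the comparison, 1550 with 3 against 3 and 60 without cycling cells. Leaving out a library gave 1 to 42, with the lone library left assumed to vary like the others. The 111 of the mean became 190 in the blocked fit, 301 with DESeq2 (108 shared), 21 with UMI gates, 895 without a filter, 1342 in the pairs (101 shared) and 698 in the replicate 1 libraries (92 shared), and 14 to 96 without a library. The 0 in WT became 100 in the blocked fit, 114 with DESeq2, 3 with UMI gates, 245 without a filter and 0 to 1 without a library. The 0 for Bcl6 KO became 11 without a filter and stayed at 0 to 0 without a library. The other alternatives kept each count within 1.5 times.

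The Treg-like share difference of -33.6 points was -27.4 with UMI gates, -35.7 with at least 2000 UMIs, and -40.4 to -30.2 without a library (exact permutation p 0.00926 to 0.0370). In the blocked permutation it was -26.2 at the smallest p its arrangements allow, so the design ends that call. The CD8 T-like share difference stayed between 4.39 and 11.9 points without a library. For Treg-like shares against Cd4Cre the difference without a library stayed between -25.7 and -8.17 in Prdm1 KO and between -13.5 and -1.41 in Bcl6 KO. With UMI gates it was -16.7 in Prdm1 KO and -16.9 in Bcl6 KO, and with at least 2000 UMIs -10.5 and -7.63. No setting could give a call, since the smallest exact permutation p that the arrangements allow is 0.167 or higher.

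Of the named genes, 1 reversed, Cdk1 in Treg-like cells of Prdm1 KO, at -0.54 without cycling cells, where the alternative removes the cells that carry it. In that comparison 763 pairs of a named gene and an alternative kept call and direction and 317 lost the call. For the mean of 4 genotypes in Treg-like cells 532 kept both and 276 lost the call. In CD4 Tconv-like cells, where no named gene was called as reported, the log2 change turned sign uncalled in 63 pairs for the mean, 39 for Prdm1 KO, 27 for WT and 24 for Bcl6 KO, and in 22 and 7 for the differences of effects of Bcl6 KO and Prdm1 KO. For Prdm1 KO there 3 named genes stayed uncalled with the same direction in all alternatives and 43 did not. Of the pairs of a named gene and an alternative in that comparison, 547 stayed the same and 103 gained a call in the same direction. The blocked fit changed no call other than those given beside the results. Depth limits genes with few counts, such as Slfn4, Calca and Fcrl6.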

Other observations

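The splits of the libraries were counted after the results were seen, and the test of flanking DNA was written before. In Treg-like cells 6 of 100 splits of treatment within genotype, the real one included, gave as many genes as the real 111, with 1736 as the highest other, so over all splits chance cannot be excluded. The 5 other splits as large have 3 or 4 replicate 2 libraries in the treated arm against 1 in the real one and follow the replicate number. Replicate 2 libraries were counted with Cell Ranger 7.0.0, and replicate 1 libraries with 3.0.2 or, for Prdm1 KO, 3.1.0. Of the 26 other splits with 1 replicate 2 library 0 were as large and the highest count was 1, and the blocked fit called 190. In CD4 Tconv-like and CD8 T-like cells the real count was 0, so 100 of 100 splits are as large whatever the data, and the count says nothing about chance. The highest others were 3421 and 3153, in splits that follow the replicate number too. Splits with so many calls point to a structure of the samples.

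DNA of another strain left around a targeted locus may change genes near it. Of the 51 genes tested within 10 Mb of Prdm1 in Treg-like cells 1 was called, or 1.96% against 3.72% elsewhere, a ratio of 0.5267 (95% interval 0.0755 to 3.68, two-sided Fisher's exact p = 1). The interval leaves a share above that elsewhere open, so the test does not decide.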
